A study of Mus musculus with 12 samples.

How the data were processed

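Thymus total RNA from mice aged 7 to 8 weeks had been hybridized to 12 one-colour Affymetrix mouse arrays in 4 groups of 3 biological replicates. The groups crossed the sex chromosome complement (XX, or an XY marked as carrying a Y without Sry per the labels) with gonadal sex, male in the groups labelled as carrying Sry. Biotin-labelled cRNA was made from 10 µg of RNA per the labels. The deposited values were log2 probe set values made by the authors with RMA, per the submitters' processing notes, and the RMA version is not given in the sources used here. The array medians lay between 4.02 and 4.10. The number of arrays limits precision: the median standard error of an autosomal probe set was 0.054 for a main effect, 0.0764 for an effect within 1 complement or 1 gonadal sex, and 0.108 for the interaction.

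Of 45101 probe sets, 64 controls were left out, and 17925 with a mean log2 value of at least 5 over the 12 arrays were tested. The platform gene table named 35890 probe sets, 34958 with 1 gene symbol and 932 with several, and 9211 were not named. Single-gene probe sets were matched by Entrez ID to the RefSeq genes of assembly GRCm38.p6, which placed 34754 and left 204 without a match. The tested set held 15765 probe sets with 1 symbol for 9496 genes: 15278 autosomal probe sets, 458 on X, 2 on Y and 2187 without a chromosome, which includes unnamed and several-gene probe sets.

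Group means were fitted in R 4.3.3 with limma 3.58.1, and contrasts were tested with moderated t statistics (8 residual and 3.71 prior degrees of freedom) and a Benjamini-Hochberg adjusted p under 0.05. The complement effect was XX minus XY averaged over gonadal sex, the gonadal sex effect was male minus female averaged over complement, and the interaction was the complement effect in females minus that in males. Both effects were also taken within each level of the other factor, and XX females were compared with XY males. Of 31 gene lists fixed before the data were examined, the 25 with at least 5 measured genes were tested with camera in limma, using 1 probe set per gene (the highest mean) and a preset inter-gene correlation of 0.01. Sets of genes by chromosome were tested in the same way. Comparisons, tests, thresholds and most alternatives were fixed at that point too. Figures were drawn with matplotlib 3.10.9.

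The genes named were chosen by a fixed rule. It took the 12 genes with the smallest p in each direction for each main effect, the 8 autosomal genes with the smallest p in each direction, and the 5 smallest in each direction for the other contrasts. It also took each list member past the threshold, or the highest-expressed members of a list where none passed. Other names are marked as chosen after their values were seen.

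The fit was tested on simulated data with 17925 probe sets, 200 of them changed. At a log2 difference of 0.5 it recovered 98% for the complement effect, 97.5% for the gonadal sex effect, 43% for the interaction and 85% for the complement effect in females; at 0.3 these shares were 74%, 71.5%, 0% and 7%. False calls at 0.5 were 13 of 209, 11 of 206, 3 of 89 and 10 of 180 calls, in that order. At a difference of 1 they were 17 of 216 for the complement effect. Of 10 lists shifted by 0.2, 10 were recovered, with 1 false call. The simulated noise was independent between probe sets, so this check could not test the preset inter-gene correlation.

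Alternatives were no filter and a stricter filter (mean log2 of at least 6), median centring, quantile normalization, an intensity trend with robust settings, array weights, 1 probe set per gene, autosomal probe sets alone, adjusted p under 0.1, a log2 difference of at least 0.5, only the groups compared, the replicate number as a block, and each array left out in turn. Lists were also tested with an estimated inter-gene correlation, with fry, and with the mean over a gene's probe sets. The actin 3' minus 5' difference as a covariate, and median centring for lists and chromosome sets, were added after the data were seen.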

Results

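Gene expression was measured in thymus on 12 arrays, with 3 biological replicates in each of 4 groups: XX females, XX males, XY females and XY males. The number of arrays limits precision.

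Xist, the RNA that coats the inactive X chromosome, was higher in XX than in XY thymus by a log2 difference of at least 5.15 (6 arrays on each side), a lower bound since the XY values lay near the bottom of the array's range. In 6 of 6 XX arrays it lay above every XY array. Other X-linked genes differed by less: Eif2s3x, a translation initiation subunit, rose by 0.66 ± 0.037 (standard error; limma adjusted p = 2.21e-06). The histone demethylases Kdm6a and Kdm5c rose by 0.61 ± 0.047 and 0.50 ± 0.043, and Pbdc1 by 0.40 ± 0.049 (adjusted p = 4.77e-05, 0.000164 and 0.00518). The Y-linked partner Eif2s3y, a gene XX mice lack, was lower in XX by at least 5.79 (adjusted p = 1.04e-09), also a bound. Pisd-ps3, a pseudogene related to a phospholipid decarboxylase, was the only other named gene past the threshold, in 1 of its probe sets, at 0.62 ± 0.092 (adjusted p = 0.0251). That probe set had no chromosome in the gene table used, so it is not counted as autosomal or X-linked, and it did not pass in 10 of 21 alternatives (adjusted p up to 0.116). Probe sets shared by Pisd-ps3 and its relatives differed by 0.70, 0.52, 0.43 and 0.24 and did not pass (adjusted p = 0.056, 0.057, 0.0926 and 0.998). Its other single-gene probe sets differed by 0.36, 0.31 and 0.14 and did not pass (adjusted p = 0.548, 0.998 and 0.998). The group means of the probe set that passed were 8.74 in XX females, 8.66 in XX males, 7.84 in XY females and 8.31 in XY males, and 5 of 6 XX arrays lay above every XY array. Also lower in XX were 3 probe sets with no gene name, singled out after their values were seen, at -6.67, -5.50 and -4.91. The Y-linked genes Kdm5d (-4.62) and Uty (-3.27) lay below the filter on low values and were lower in XX in the fit without it. These differences, too, are bounds on size, since XX values lay near the bottom of the range.

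Of 11 measured genes in the list of X escape genes, 5 rose in XX and 6 did not pass, and 8 rose when adjusted over the list alone. The 5 were Xist, Eif2s3x, Kdm6a, Kdm5c and Pbdc1, named above. The median of the 11 was 0.36 (camera adjusted p = 5e-24, and adjusted p = 0.000466 with an estimated correlation). These camera results include Xist, at 7.61 by its probe set with the highest mean, and no test left it out. The X-linked immune genes, which include Sash3 (-0.01) and Ogt (-0.01), had a median of 0.01 with 0 of 14 past (limma), and camera gave an adjusted p of 0.667. The remaining X chromosome genes were flat: 255 genes outside the escape list had a median of 0.0083.

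No autosomal probe set passed for the complement effect (limma, 0 of 15278), and 615 had an unadjusted p under 0.05, where 5% would be 763.9. The count was 6 with array weights, and 1 with the actin covariate, without XX female replicate 3 and without XY female replicate 2. The autosomal genes with the smallest p were Fgr, a myeloid kinase (0.23 ± 0.044, adjusted p = 0.182), Ly6k (0.96 ± 0.218, adjusted p = 0.595, and past in 3 of 22 alternatives) and Ccdc86 (0.20 ± 0.044, adjusted p = 0.595) on the higher side. On the lower side were Slc38a2, an amino acid transporter (-0.19 ± 0.039, adjusted p = 0.361), and Tob2 (-0.19 ± 0.045, adjusted p = 0.75). The 95% interval of this average over gonadal sex lay within 0.5 of zero for 99.4% of autosomal probe sets. For the complement effect within females and within males the shares were 94.8% and 95.4%. Chromatin lists did not pass: heterochromatin and DNA methylation genes, with Lbr at -0.02 and Trim28 at -0.03, had a median of -0.02 (0 of 28 past; camera adjusted p = 0.343). Polycomb genes had a median of 0.02 (0 of 18; adjusted p = 0.343), and histone demethylases and methyltransferases 0.01 (0 of 19; adjusted p = 0.818). Among lists of cell types and other programmes, camera called B cells higher in XX (median 0.18, adjusted p = 0.00156; adjusted p = 0.583 with an estimated correlation). It called fat genes higher (0.14, adjusted p = 0.0326; adjusted p = 0.813 with an estimated correlation) and imprinted genes lower (-0.06, adjusted p = 0.0326; adjusted p = 0.583 with an estimated correlation), with 0 members of any past. The other lists had camera adjusted p of 0.0522 or higher. For fat 1 array stood apart: the mean over its genes, centred on all arrays, was 0.571 in XX male replicate 2. It was -0.390 and -0.015 in the other XX male arrays. The count for the complement effect was 16 probe sets, 12 higher and 4 lower; without XY male replicate 3 it was 10.

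**Figure D1:**
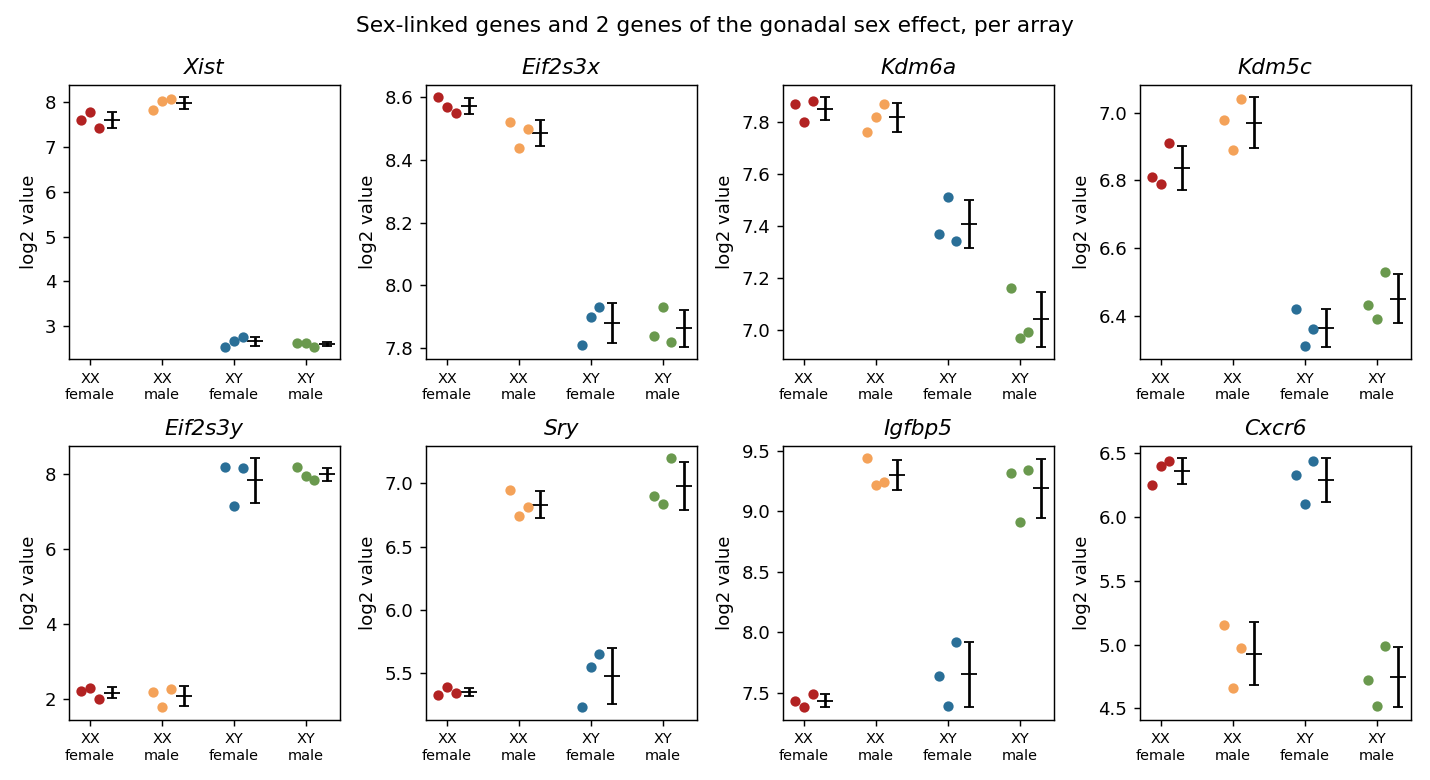
Log2 values of sex-linked and gonadal sex genes, 1 point per array, with the group mean and standard deviation beside them. Xist and Eif2s3y separated XX from XY, and Sry, Igfbp5 and Cxcr6 separated males from females, each with no overlap between arrays.

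In gonadal males, Sry, the gene that sets testis development, rose by at least 1.49, a bound since females labelled without Sry give only a background level. Igfbp5, a binding protein for insulin-like growth factors, rose by 1.70 ± 0.096 (6 arrays on each side; limma adjusted p = 7.2e-06 for both). Kcnk2 (0.91 ± 0.065), Nqo1 (0.87 ± 0.073), Slc46a2 (0.74 ± 0.072), Ltbp3 (0.64 ± 0.053), Fgfr2 (0.62 ± 0.052) and Isl1 (0.60 ± 0.048) rose as well. The chemokine receptors Cxcr6 and Cxcr3, found on effector and innate-like lymphocytes, fell by 1.49 ± 0.099 and 1.14 ± 0.079 (adjusted p = 3.01e-05 and 3.52e-05). Icos (-0.78 ± 0.066), Cxcl10 (-0.89 ± 0.078), Nkg7 (-0.68 ± 0.064), Cd44 (-0.64 ± 0.069), Id2 (-0.59 ± 0.044) and H2-T24 (-0.55 ± 0.042) fell. In all, 1176 probe sets passed, 708 higher and 468 lower, and 1015 were autosomal. The balance depended on the fit: it was 394 higher and 471 lower with the actin 3' minus 5' difference, a sign of RNA quality, as a covariate, and 44 higher and 80 lower at a log2 difference of at least 0.5. With the actin covariate 865 probe sets passed, and only 527 of them were among the 1176, so many calls were lost and others gained. Differences were small: the median size of the called differences was 0.265, and 83 exceeded 1.5-fold. Of the 1176, 130 also passed in XX, 715 in XY and 65 for the interaction. The count was 600 without XX female replicate 1, 729 without replicate 2 and 665 without replicate 3 of that group, 680 and 538 without XY male replicates 1 and 3, and 580 and 516 without XX male replicates 2 and 3.

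Interferon response genes, which mark type I and type II interferon signalling, were the list with the smallest p. List members are given by their probe set with the highest mean, which for Isl1 and Cd44 is not the one with the smallest p named above. Of 24 measured, 0 rose and 17 fell in males, including Cxcl10, Cxcl9 (-0.75), Rtp4 (-0.46) and Ifi27l2a (-0.39), and 20 fell when adjusted over the list alone. The median was -0.29 (camera adjusted p = 1.13e-19, and adjusted p = 0.164 with an estimated correlation). Mature single-positive thymocyte genes, which mark cells about to leave the thymus, fell in 11 of 21 (Ms4a4b -0.58, Ccl5 -0.50, Ccr7 -0.33), with Bcl2 rising by 0.29. The list lay lower in males (median -0.21, camera adjusted p = 4.54e-12, and adjusted p = 0.164 with an estimated correlation). Of 9 B cell genes 0 rose and 4 fell (Pou2af1 -0.80, Ms4a1 -0.59, Ighm -0.53, Jchain -0.50). As a list these genes were lower (median -0.35, camera adjusted p = 3.52e-08, and adjusted p = 0.164 with an estimated correlation). Innate-like T and natural killer genes had 3 of 6 lower (Cxcr6, Klrd1 -1.26, Il2rb -0.37) and Gzma higher at 0.20. The group as a whole was lower (median -0.31, camera adjusted p = 2.18e-05, and adjusted p = 0.164 with an estimated correlation). Regulatory T cell genes had 3 of 8 lower (Izumo1r -0.48, Capg -0.37, Tnfrsf4 -0.34) and Il2ra higher at 0.56. Together they were lower (median -0.10, camera adjusted p = 0.0285, and adjusted p = 0.356 with an estimated correlation). Dendritic cell and macrophage genes such as Cd74 (-0.03) and H2-Aa (-0.04) had 0 of 17 past (limma). The list shift was downward (median -0.15, camera adjusted p = 1.52e-05, and adjusted p = 0.373 with an estimated correlation). Neutrophil genes had 0 of 7 past and 5 lower when adjusted over the list alone (S100a8 -1.33, S100a9 -1.40). As a group they were lower (median -1.03, camera adjusted p = 0.000212, and adjusted p = 0.356 with an estimated correlation). Their scores overlapped between the sexes, from -0.13 in XX female replicate 3 to 1.34 in XY female replicate 3 among females, and from -0.995 to 0.119 among males. Under the alternatives the median ran from -1.18 to -0.295, the latter with no filter on low values. A score is the mean over a list's genes in an array, centred on all arrays. B cell scores overlapped too (XX male replicate 1 at 0.162, females from 0.022 to 0.317). So did dendritic cell and macrophage scores (XX male replicate 1 at 0.117, females from -0.050) and regulatory T cell scores. Interferon, mature single-positive and innate-like scores did not overlap.

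Cortical epithelium genes, which support early thymocytes, moved the other way: 4 of 17 rose (Isl1 0.69, Il7 0.45, Dll4 0.27, Cxcl12 0.21) and 0 fell. The list was higher (median 0.11, camera adjusted p = 0.0081, and adjusted p = 0.357 with an estimated correlation). Cell cycle genes rose in 2 of 22 (Mcm6 0.20, Ung 0.19), and in 8 when adjusted over the list alone. The list was higher (median 0.13, camera adjusted p = 5.17e-05, and adjusted p = 0.4 with an estimated correlation). In medullary epithelium genes, Krt17 fell (-0.28; 1 of 10; median -0.10, camera adjusted p = 0.00276, and adjusted p = 0.357 with an estimated correlation). Among tissue-restricted antigens Csn2 fell (-0.50; 1 of 5; 2 of the 5 also neutrophil genes; median -0.50, camera adjusted p = 0.00278, and adjusted p = 0.19 with an estimated correlation). Under the alternatives that median ran from -0.549 to -0.109, the latter with no filter. Double-positive thymocyte genes had Rag2 lower (-0.19; 1 of 18; median -0.04, camera adjusted p = 0.0085, and adjusted p = 0.427 with an estimated correlation). Immediate early genes respond within minutes to handling or receptor signals. Their list, which also held heat shock genes, had 4 of 16 lower (Jun -0.52, Btg2 -0.52, Nr4a1 -0.27, Junb -0.24). The set lay lower (median -0.06, camera adjusted p = 0.00276, and adjusted p = 0.356 with an estimated correlation). X-linked immune genes had Cxcr3 and Cfp (-0.33) lower and Elf4 (0.17) higher, 3 of 14 in all. The list lay lower in males (median -0.05, camera adjusted p = 0.0495, and adjusted p = 0.406 with an estimated correlation). Of the lists in this paragraph only cortical epithelium scores did not overlap between the sexes. The immediate early and heat shock score of XX male replicate 1 (0.265) was the highest of all arrays.

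The other lists were not called for gonadal sex by camera. Single members passed in heterochromatin genes (Dnmt1 0.23; adjusted p = 0.122), histone demethylases (Kdm5b -0.24; adjusted p = 0.928) and X escape genes (Bgn -0.21; adjusted p = 0.724). Of 13 double-negative thymocyte genes 3 rose (Il2ra 0.56, Notch1 0.31, Notch3 0.31) and 2 fell (Il7r -0.52, Cd44 -0.33; adjusted p = 0.928). In fibroblasts and vessels 4 of 13 rose (Fn1 0.64, Lum 0.48; adjusted p = 0.998), and in glucocorticoid genes 3 of 16 rose (Fkbp5 0.40, Klf9 0.32) and 2 fell (adjusted p = 0.649). In the circadian clock 2 of 9 rose (Dbp 0.32, Cry2 0.24) and 1 fell (adjusted p = 0.436), and of 10 imprinted genes 3 rose (Grb10 0.39, Airn 0.23; adjusted p = 0.336). Polycomb (adjusted p = 0.998), fat (adjusted p = 0.928) and the list of sex steroid receptors and responsive genes (adjusted p = 0.928) had 0 past in limma. That last list held Nrip1 (0.07) and also Nr3c1 (0.16), the gene of the glucocorticoid receptor. For X escape genes, histone demethylases, double-negative thymocytes and fibroblasts the median and mean were above zero while the test pointed down. For fat only the median was above zero, and for glucocorticoid genes only the mean. Lists for tissue next to the thymus were too small to test by camera. Of 3 measured parathyroid and thyroid genes, the parathyroid hormone gene Pth rose in males by 1.02 ± 0.179 (limma adjusted p = 0.00838) and Chga by 0.63 ± 0.117 (adjusted p = 0.0113). Of 2 measured genes listed for lymph node tissue, Ltb fell by 0.23 (adjusted p = 0.021). Whether these genes marked tissue outside the thymus was not tested. The muscle genes Mylpf (0.08) and Eno3 (-0.11) and the red cell gene Bpgm (0.02) did not pass.

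**Figure D2:**
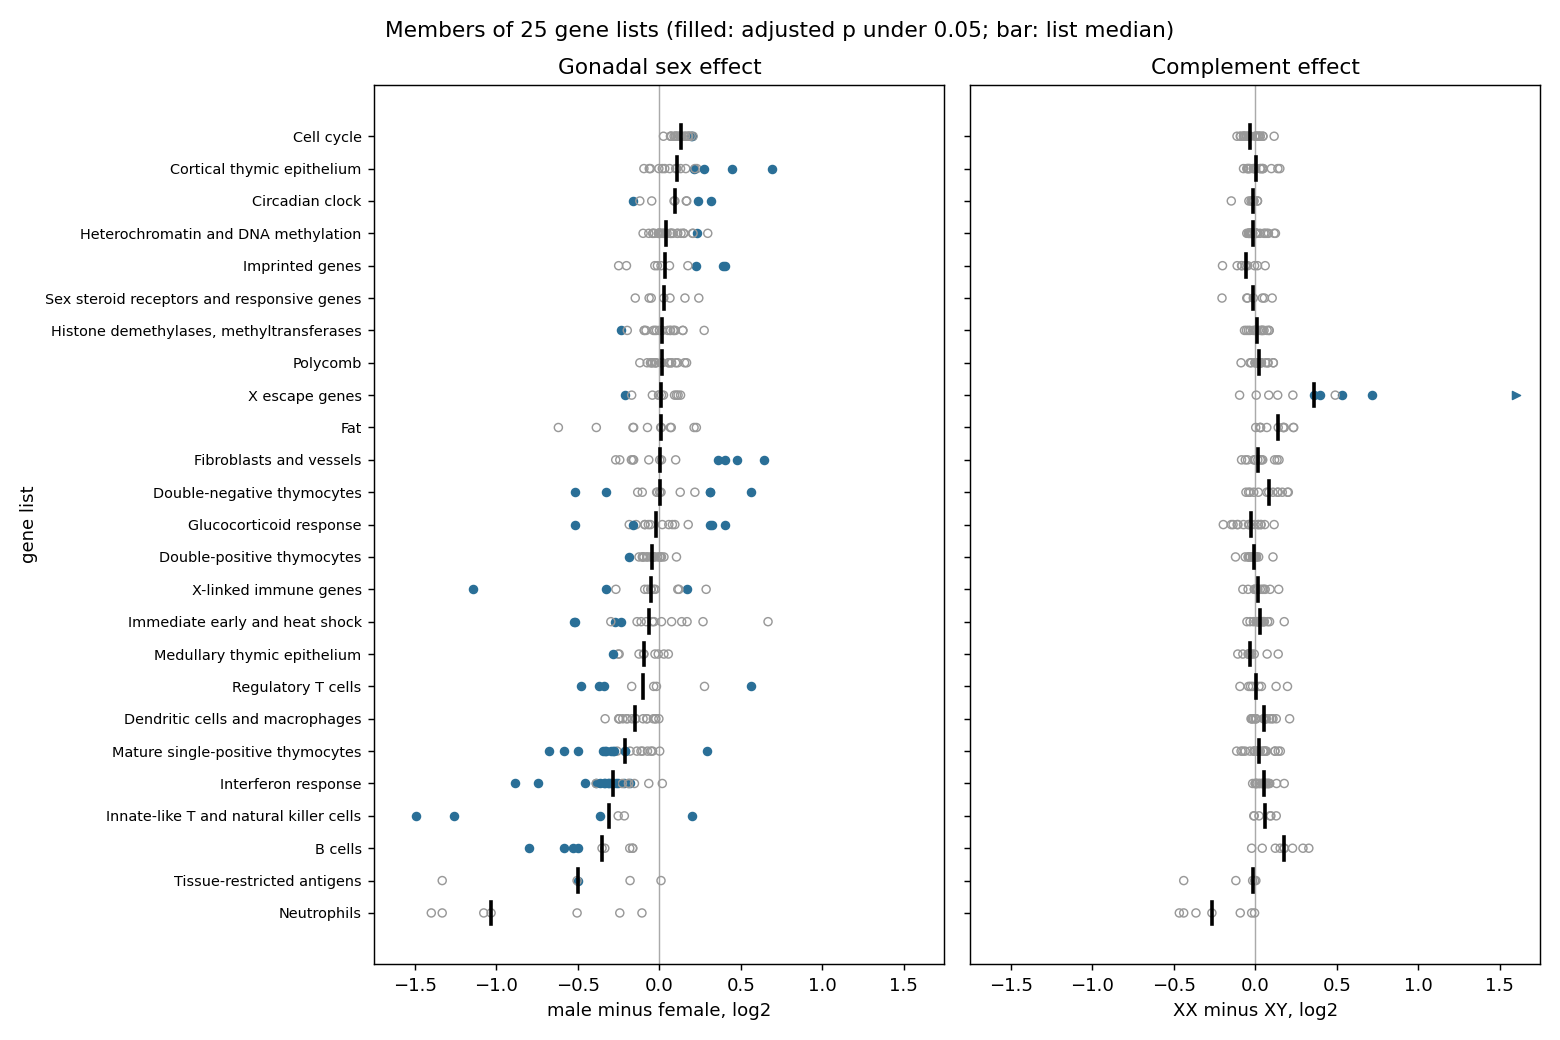
Log2 differences of the measured members of 25 gene lists for gonadal sex (male minus female) and complement (XX minus XY); points are genes, filled where the adjusted p was under 0.05, and bars are list medians. Xist lay beyond the axis and is drawn as a triangle at its edge; immune lists lay to the left for gonadal sex.

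Within XX, gonadal sex changed 133 probe sets, 70 higher and 63 lower in males (limma; 3 arrays per group). Igfbp5 (1.87 ± 0.136), Sry (at least 1.48), Kcnk2 (0.99 ± 0.092) and Enpp5 (0.58 ± 0.061) rose. Cxcr6 (-1.44 ± 0.140), Cxcr3 (-1.16 ± 0.112), Ttc39a (-0.71 ± 0.065) and A630023P12Rik (-0.66 ± 0.072) fell (adjusted p = 0.00176 for the last). The count was 54, 43 and 52 without XX female replicates 1, 2 and 3, 37 and 41 without XX male replicates 2 and 3, and 75 and 222 without XY female replicates 1 and 2. Within XY, 1549 passed, 766 higher and 783 lower (limma; 3 arrays per group). Igfbp5 (1.54 ± 0.136), Ltbp3 (0.71 ± 0.075) and Fkbp5 (0.51 ± 0.057) rose. Cxcr6 (-1.55 ± 0.140), Id2 (-0.84 ± 0.062), H2-T24 (-0.83 ± 0.060) and Timp3, an inhibitor of matrix proteases (-0.79 ± 0.078), fell. With each array centred on its median the split was 1277 higher and 685 lower, and at a log2 difference of at least 0.5 it was 84 higher and 431 lower. These groups also differed in the actin 3' minus 5' difference (0.79 in XY males, 0.63 in XY females). With it as a covariate 54 probe sets passed, and with only these groups in the fit 72 passed. The count was 575 and 553 without XY male replicates 1 and 3. Both sex effects passed together for 40 higher probe sets, where 2.99 would fall together by chance, and for 45 lower, against 2.75. Across 15278 autosomal probe sets the sex effects in XX and XY, which share no arrays, had a Pearson correlation of 0.233 (jackknife standard deviation 0.151; 0.143 without XY female replicate 3) and the same sign in 58.2%.

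**Figure D3:**
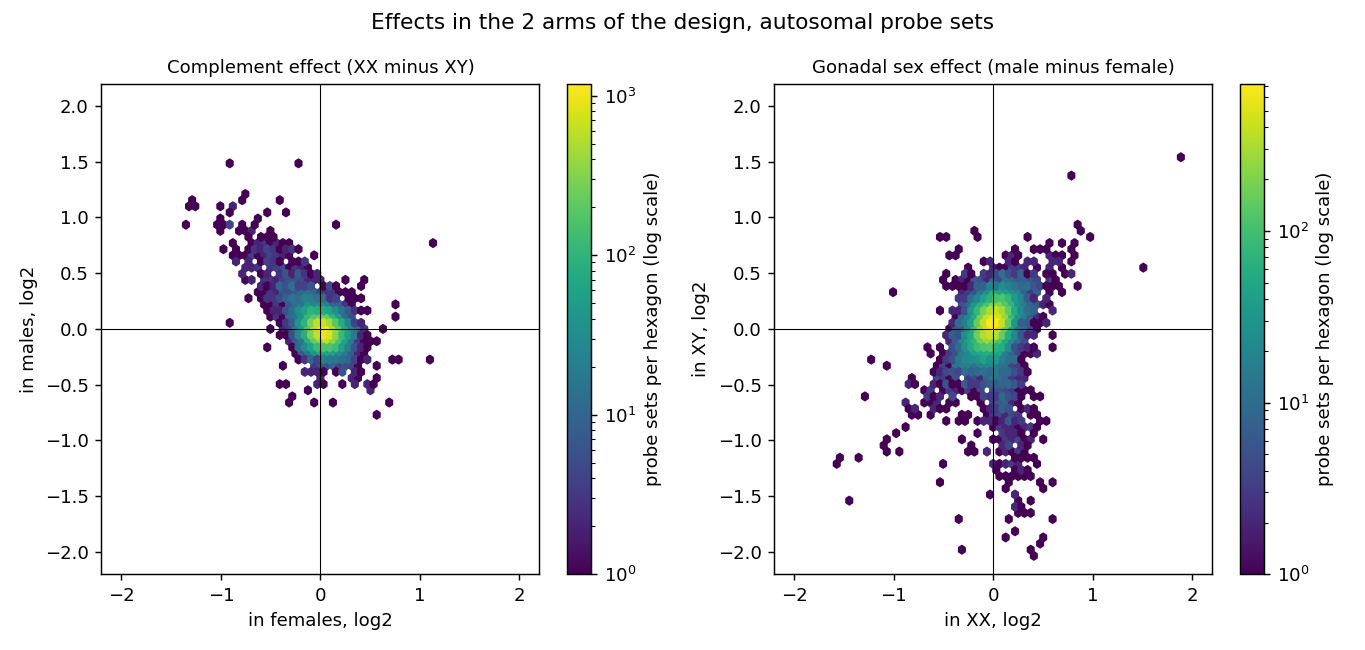
Autosomal probe sets by complement effect (females on the horizontal, males on the vertical axis) and by gonadal sex effect (XX and XY), as log2 differences, coloured by the number of probe sets per hexagon. Complement effects sloped downward, and a group of probe sets was lower in XY males than in XY females with little difference in XX.

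Complement effects in females and in males both held Xist (at least 4.93 and 5.37), Eif2s3x (0.69 ± 0.053 and 0.62 ± 0.053), Kdm5c (0.47 ± 0.061 and 0.52 ± 0.061) and, lower in XX, Eif2s3y (-5.66 and -5.91, as bounds), at 3 arrays per group. In females 14 probe sets passed (limma), 10 higher and 4 lower, with 0 autosomal, and without XY female replicate 3 the count was 9. At unadjusted p under 0.05 (limma) there were 1568 autosomal probe sets in females and 1181 in males, where 5% would be 763.9. In males 23 passed, 19 higher and 4 lower, and 8 were autosomal, including Slc25a30, a mitochondrial carrier (0.72 ± 0.093, adjusted p = 0.00809). That count was 15 without XX female replicate 1 or 2, and 10, 151 and 10 without XY male replicates 1, 2 and 3. It was 12 without XX male replicate 3, and 11 and 200 without XY female replicates 1 and 2. Across autosomal probe sets the complement effects in females and males had a Pearson correlation of -0.496 (jackknife standard deviation 0.15), with the same sign in 39.5%.

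XX females differed from XY males in 249 probe sets, 140 higher and 109 lower (limma). Xist (at least 4.99), Cxcr6 (1.62 ± 0.140), Kdm6a (0.81 ± 0.067) and Ttc39a (0.77 ± 0.065) were higher in XX females. Eif2s3y (-5.82, a bound), Igfbp5 (-1.76 ± 0.136), Sry (-1.63, a bound) and Kcnk2 (-0.85 ± 0.092) were lower, at 3 arrays per group. The count was 81, 73 and 102 without XX female replicates 1, 2 and 3, 90 and 76 without XY male replicates 1 and 3, 150 without XX male replicate 3, and 633 without XY female replicate 2.

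For the interaction, Lmnb1, a nuclear lamina gene, was higher at 0.94 ± 0.129 (limma adjusted p = 0.0213), with Arglu1 (1.35 ± 0.216), Prpf19 (1.07 ± 0.175), Rraga (0.86 ± 0.145) and Ywhab (0.64 ± 0.108; adjusted p = 0.0246 for these). Plpp3 (-0.72 ± 0.091), Slc25a30 (-0.98 ± 0.131), Ccdc88c (-0.81 ± 0.108), Nlk (-0.70 ± 0.096) and the transcription factor gene Zbtb20 (-0.98 ± 0.135) were lower (adjusted p = 0.0213). In all, 232 probe sets passed, 48 higher and 184 lower, and 177 were autosomal. With the actin 3' minus 5' difference as a covariate 1 passed, and with 1 probe set per gene 15 passed. Camera called dendritic cell and macrophage genes (median -0.14, adjusted p = 5.33e-05), fibroblasts and vessels (-0.08, adjusted p = 0.00593), medullary epithelium (-0.08, adjusted p = 0.0411) and glucocorticoid genes (-0.05, adjusted p = 0.0499), each with adjusted p = 0.809 with an estimated correlation. Without XY female replicate 3, 3 of these calls were lost. Its scores stood above the rest of its group: 0.268 against 0.021 and -0.050 for dendritic cells and macrophages, and 0.242 against 0.020 and -0.020 for medullary epithelium. Probe sets for the 3' and 5' ends of actin, a sign of RNA quality, differed by 0.63 in XY females, 0.79 in XY males and 0.73 in both XX groups. For a second control gene, Gapdh, the difference spread less, from -0.07 in XY female replicate 2 to 0.03 in XY male replicate 1. The same arrays lay at the ends for actin (0.51 and 0.83). The Gapdh difference was not used as a covariate. XY female replicate 2 stood apart, with the lowest correlation within any group (0.9832, with replicate 3), an actin difference of 0.51 and a limma array weight of 0.204. The count was 0, 37 and 12 without XX female replicates 1, 2 and 3. It was 1, 390 and 0 without XY male replicates 1, 2 and 3, and 99, 0 and 0 without XX male replicates 1, 2 and 3. It was 79 and 451 without XY female replicates 1 and 3, and 222 without XY female replicate 2.

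**Figure D4:**
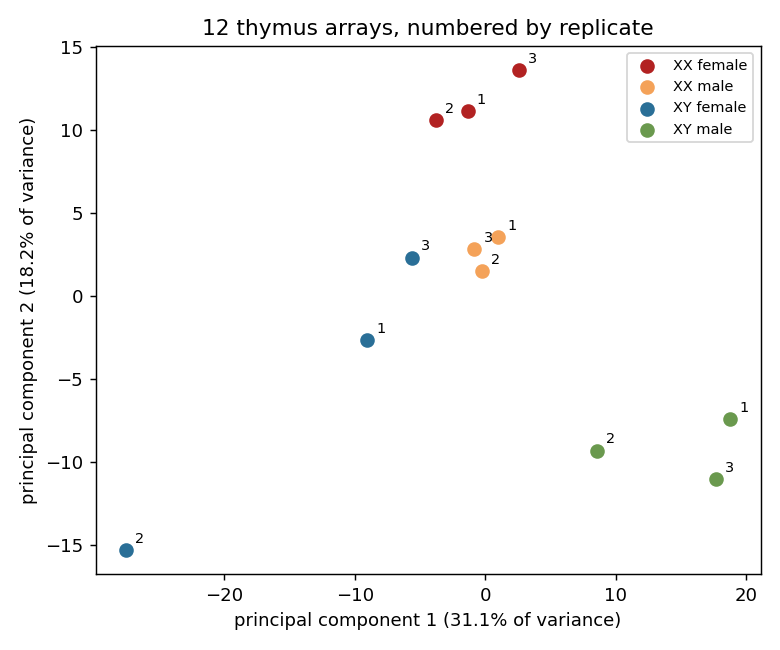
Principal components 1 and 2 of the 12 arrays, with 31.1% and 18.2% of the variance; each point is an array, numbered by replicate. XY females and XY males lay at opposite ends of component 1, with the XX groups between.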

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

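The test on genomic span, and its comparison with the gonadal sex calls, were chosen after the result was seen. The complement effect differed between gonadal females and males in 232 probe sets (limma). Among genes named for the main effects, the effect differed between the sexes for Trio (-0.737, adjusted p = 0.0213), H2-T24 (-0.553, adjusted p = 0.0213), Id2 (-0.513, adjusted p = 0.0246), Junb (-0.497, adjusted p = 0.0405), Btg2 (-0.983, adjusted p = 0.0405) and Cd44 (-0.680, adjusted p = 0.0405). For Cd44 this was the probe set with the smallest p for gonadal sex, and the one with the highest mean did not pass. In 3 of 3 XY male arrays Trio, H2-T24, Id2, Junb and Cd44 lay below every other array, and Btg2 did in 2 of 3. Male minus female differences in XY and in XX were -0.67 and 0.06 for Trio, -0.84 and -0.33 for Id2, and -1.01 and -0.03 for Btg2. By camera, the effect also differed for medullary epithelium (median -0.083, adjusted p = 0.0411), dendritic cells and macrophages (-0.143, adjusted p = 5.33e-05), fibroblasts and vessels (-0.083, adjusted p = 0.00593) and glucocorticoid genes (-0.053, adjusted p = 0.0499), each with adjusted p = 0.809 with an estimated correlation. These list calls leaned on XY female replicate 3: 3 of them were lost without that array.

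The counts argue against XY female replicate 2 as the only cause, since 222 probe sets passed without it, 179 of them among the 232, although 0 passed without any 1 of several other arrays. RNA integrity remains open: with the actin difference as a covariate the median size of the called differences went from 0.975 to 0.679, a ratio of 0.696, and 1 call remained, with the standard error at 0.174 and 0.175. The 119 genes called lower were long, with a median genomic span of 56.5 kb against 23.4 kb for tested genes, at percentile 100 of 10000 random sets. Of the lower calls 25.5% had no single gene symbol (unnamed or several genes), against 12.1% of tested probe sets. More unspliced or nuclear RNA in XY females than in XY males could give this, but genes higher in gonadal males also reached percentile 100 (30.7 kb), and across 9478 genes the Spearman correlation of span with the interaction was 0.0185. A mixture of RNA composition and biology is possible, and these 12 arrays do not separate them.

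Arrays were also regrouped with equal group sizes, a plan made before the values were seen. For the main effects and the interaction the other groupings were drawn at random, separately for each, and are not all of those possible. In a regrouped fit the real differences between groups enter the residual spread, which can make calls harder to reach. The low counts of other groupings are therefore not a rate of calls from noise alone. For the interaction 1 of 100 groupings, the real one, gave 232 calls, and the highest other gave 1. For gonadal sex 1 of 100 gave as many as the real 1176, and the highest other gave 92. For complement 2 of 100 gave as many as the real 16, and the other gave 232, since swapping complement within 1 sex turns the complement contrast into the interaction. The like swaps that turn the gonadal sex contrast into the interaction, or the interaction into a main effect, were not among those drawn, so the highest other values of 92 and 1 leave them out. Within 1 sex or complement the 10 splits are too few for a share under 0.05; the real split, 1 of them, gave 14 in females, 23 in males, 133 in XX, 1549 in XY and 249 for XX females against XY males, and the highest other gave 0, 0, 0, 6 and 0.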

How the results depend on the processing

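The actin covariate, and median centring for gene lists and chromosome sets, were chosen after seeing the data; the other alternatives were planned. Among the named genes and the gene lists, none past the threshold in the main analysis passed in the opposite direction under an alternative, but many calls were lost. Other called probe sets were not checked for this. Of 179 results for named genes 112 stayed on the same side of the threshold under every alternative. Calls for gonadal sex were lost for Ifit2 in 14 of 22 alternatives, Irf9 in 13 of 22, Xaf1 and Gzma in 12 of 22, Elf4 in 13 of 20 and Bgn in 12 of 21. Medians did cross zero: that of glucocorticoid genes for the interaction went from -0.053 to 0.061 without XY female replicate 3, and that of fibroblasts and vessels for gonadal sex, which was not called, ran from -0.077 to 0.057. For gonadal sex the larger side turned, from 708 higher and 468 lower to 394 and 471 with the actin covariate and to 44 and 80 at a log2 difference of at least 0.5. The cause of a change was not tested unless stated.

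With array weights, which gave XY female replicates 1, 2 and 3 weights of 6.67, 0.204 and 0.578, so that this group rested mainly on 1 array, calls rose to 30 for complement, 4361 for gonadal sex, 1272 for the interaction, 1477 and 522 for complement in females and males, 1320 and 4245 for sex in XX and XY, and 1168 for XX females against XY males. With the actin covariate the interaction had 1 call and sex in XY 54. Gonadal sex had 865, with 527 of them among the 1176 calls of the main analysis.

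With no filter on low values, calls were 26 for complement, which brought in Y-linked genes, 692 for gonadal sex and 24 for complement in females; 7 lists passed for complement and 2 for the interaction. The stricter filter gave 9 for complement in females and 15 in males. With an intensity trend and robust settings, complement had 23 in females and 48 in males, and XX females against XY males 383.

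With 1 probe set per gene, calls were 7 for complement, 15 for the interaction, 6 and 7 for complement in females and males, and 698 for sex in XY. With autosomal probe sets alone, complement had 0, 0 in females and 2 in males, against 0, 0 and 8 autosomal calls in the main analysis.

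At adjusted p under 0.1, calls by construction rose to 2355 for gonadal sex, 482 for the interaction, 24 and 73 for complement in females and males, 249 and 2772 for sex in XX and XY, and 644 for XX females against XY males. With a log2 difference of at least 0.5 they fell to 124 for gonadal sex, 80 and 515 for sex in XX and XY, and 114 for XX females against XY males. With only the groups compared, complement had 7 in females and 70 in males, and sex 216 in XX and 72 in XY.

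Replicate numbers were not taken as pairs in the main fit. Of 18 pairs of same-numbered arrays 8 had a correlation over 0.1 (range -0.0827 to 0.306, median 0.0413), so a shared effect of replicate number is not excluded. As a block, replicate numbers gave 377 calls for the interaction, against 232 in the main fit. For complement in females and males they gave 25 and 120, against 14 and 23.

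For lists, an estimated inter-gene correlation left 1 for complement, 0 for gonadal sex and 0 for the interaction. With fry these were 1, 7 and 0. Median centring gave 8 for complement, and the mean over a gene's probe sets gave 1 for the interaction.

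With each array left out in turn, calls ran from 10 to 19 for complement, 516 to 1745 for gonadal sex, 0 to 451 for the interaction, 9 to 17 and 10 to 200 for complement in females and males, 37 to 222 and 553 to 1525 for sex in XX and XY, and 73 to 633 for XX females against XY males. Lists past ran from 3 to 9 for complement, 11 to 14 for gonadal sex and 1 to 7 for the interaction. The correlation of the complement effects in females and males ran from -0.526 to -0.348, and that of the sex effects from 0.143 to 0.342.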

Other observations

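The tests on cell content that compare lists, the Pisd test, the distal X test, and the globin probe sets were chosen after the result was seen. Probe sets shared by alpha globin genes were higher in gonadal males by 1.44 ± 0.424 (limma adjusted p = 0.0648), 1.22 ± 0.341 (adjusted p = 0.0543) and 1.19 ± 0.326 (adjusted p = 0.0507), and the beta globin probe set by 1.19 ± 0.353 (adjusted p = 0.0657); none passed. Neutrophil genes lay in the other direction, with 7 of 7 below zero.

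In gonadal males the immune lists lay lower while cortical epithelium lay higher, so the lists did not move alike. The lists compared here were picked after those directions were seen, so the permutation p values describe the gap and are not independent support. Cortical epithelium scores lay above B cell scores by 0.546 in the male minus female difference (permutation p = 0.00216). A larger thymocyte share lowering all other cells alike would not by itself give this gap, but a partial contribution cannot be excluded. Double-positive scores lay above B cell scores by 0.355 (permutation p = 0.013). Dilution by tissue that holds neither cell type would lower both about equally, if both sets of markers respond alike. Neither condition was tested. Pth and Chga were higher in males, and the globin probe sets leaned that way without passing, so a difference in tissue content stays open. With mature T and B cell scores as covariates the median interferon difference went from -0.286 to -0.112, a ratio of 0.39, consistent with fewer mature lymphocytes carrying part of the interferon signal. The standard error rose from 0.0708 to 0.128, and lower calls in no list also shrank (ratio 0.549, 394 probe sets) while higher calls in no list did not (ratio 1.11, 666 probe sets), so the shrinkage was shared by the lower side and not specific to interferon genes.

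Distal X genes next to the pseudoautosomal region could be present in a second copy in XY mice. Of 9 such genes listed 4 were measured, and their median XX minus XY difference was 0.0167, with Tmsb4x at 0.03 (95% interval -0.0506 to 0.114), Hccs 0.02, Msl3 0.02 and Prps2 -0.02, which argues against a second, expressed copy of these 4 genes on the Y; the others were not tested.

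For Pisd-ps3, the probe set for Pisd alone differed between XX and XY by 0.07 (95% interval -0.0268 to 0.167), below the 0.62 of the Pisd-ps3 probe set that passed; the other probe sets for Pisd-ps3 alone differed by 0.36, 0.31 and 0.14 and did not pass. The passing probe set lost its call in 10 of 21 alternatives, with an adjusted p of up to 0.116.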
